A study of Homo sapiens with 4 samples.

How the data were processed

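Total RNA from human umbilical endothelial cells was extracted with a column kit, copied to cDNA from an oligo-dT primer carrying a T7 promoter and transcribed into biotin-labelled cRNA, per the labels' protocols. It was hybridised to 4 Affymetrix U133 Plus 2.0 arrays (platform per the annotation header), 1 each for cells given GFP, Akt, MAPK or PymT. The values used here are intensities on a linear scale, 1 per probe set and array, as deposited by the authors. The software and settings that made them are not given in the sources used here, and detection calls were not used here. All 4 columns had the same trimmed mean, 500.07 with 2% trimmed from each end, and no value at or below 0, so they had been scaled to a common level before deposit and were taken as deposited. Such scaling would hide a difference in total RNA per cell. Because each labelled transcript is primed at its 3' end, degraded RNA raises the 3'/5' signal ratio of control genes, and those ratios were read from the control probe sets.

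Of 54675 probe sets, 42898 were listed in the platform annotation, 41097 with 1 gene symbol and 1801 with several, and 11777 were not listed and are unnamed here. Of the probe sets with 1 symbol, 41043 were matched by gene identifier to a RefSeq gene table, and 0 symbols changed. Genes were named only from probe sets with 1 symbol. Y-linked genes, XIST and TSIX were left out of all named genes, gene counts and gene lists for donor privacy. Summaries of whole arrays and correlations of array pairs did not leave out their probe sets.

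An offset of 12.79, the pooled 25th percentile of all values, was added before log2. Probe sets passed the expression filter with a mean log2 value above 5.98, the median over all probe sets (about 50.3 intensity units), and the brightest passing probe set stood for its gene, which left 12434 genes. With 1 array per condition no test between groups is possible. Genes at least 2-fold apart were counted for all 6 pairs of arrays, and 8-fold counts are given beside them. For each of 28 gene lists the median difference of the members past the filter was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 members was called apart below percentile 0.5 or above 99.5, which describes these arrays only. Agreement between differences was measured across genes, with a simulation of 100 sets of unchanged arrays for those that share the GFP array.

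The 10 genes with the most positive and the 10 with the most negative difference from GFP were eligible to be named (5 and 5 for the other pairs), and up to 4 members per list with the greatest absolute difference. Not every eligible gene is named, and a gene whose level varies between people is not reported here for donor privacy. Kinases of the design and angiocrine list members could be named wherever measured. Groups, lists, naming rule, thresholds and 9 kinds of alternative were fixed before the data were examined: 2 other offsets, median centring, quantile normalization, no filter, a filter at the 75th percentile, the mean over a gene's probe sets, leaving out probe sets marked as matching several transcripts, and, for counts, a 3-fold threshold. The second-brightest probe set of each gene was added after seeing the data. Donor-dependent transcripts were checked across arrays, and only the number of distinct patterns is given.

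The steps were tested on simulated data with independent noise of SD 0.2 log2 units per array, a value chosen for the test. Such a test checks the steps and gives no error rate for the real arrays. For Akt against GFP over 12430 genes, 197 of 200 genes given a log2 change of 2 were recovered and 4 unchanged genes were called. For MAPK against GFP, a list shifted by 0.5 gave a median of 0.449 at percentile 100, and 3 of 200 unshifted lists were called apart. Across the pairs of arrays, 90.6% to 94.2% of genes at least 2-fold apart that had a second probe set past the filter differed in the same direction there, and 53.2% to 60.7% also by 2-fold. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.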

Results

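The series compared human umbilical endothelial cells, primary cells that line vessels of the umbilical cord, under 4 conditions. A culture that received green fluorescent protein (GFP) was the control, and the others carried activation of Akt, of MAP kinase (MAPK) or of PymT, the usual abbreviation of the polyoma virus middle T antigen. Which constructs were used is not stated in the sources used here. Each condition was measured on 1 oligonucleotide array with 54675 probe sets, so no difference below has a replicate check, no p-value is given, and the number of arrays limits the precision. The deposited intensities had medians of 53.4 in the GFP, 55.6 in the Akt, 57.2 in the MAPK and 51.1 in the PymT array, and maxima between 34987 and 42555. Across the 27337 probe sets past the expression filter, log2 values of array pairs correlated with r between 0.917 and 0.931 (across probe sets, which are not independent replicates). After that filter 12434 named genes remained, and differences are in log2(intensity + 12.79), which understates those of dim genes. Many genes named below had no further probe set past the filter, so their differences rest on a single probe set. For genes with a further probe set, the difference between 2 arrays read from the brightest and from the second-brightest probe set disagreed by a median of 0.30 to 0.35 log2 units, depending on the pair of arrays, and these data hold no other measure of error.

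Transcripts whose level depends on the donor more than on treatment fell into 3 distinct patterns among the 4 arrays, so the cultures did not all share a donor or donor pool, and condition and donor cannot be told apart. The 3'/5' signal ratio of beta-actin, a measure of RNA and labelling quality, was 1.49 in the GFP, 1.30 in the Akt, 1.57 in the MAPK and 1.61 in the PymT array. For GAPDH the ratios were 1.05, 0.92, 1.22 and 0.88 in the same order. Of 81 list medians against GFP, 40 lay outside the central range of random lists, where 0.81 would by chance if list members varied independently, which genes of a pathway do not. Some genes also sit in several lists, as the urokinase receptor gene PLAUR does in those of ERK targets, tip cell genes and proteases. The calls are therefore not separate evidence. The same GFP array enters all 81, so a list called in the same direction in each comparison may reflect that array alone.

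The design named kinases, so their transcripts and the genes that ERK signalling induces were read first. The AKT1 intensity was 1737 in the Akt array and 2018 in the GFP array, and MAPK3 (ERK1) read 1442 in the MAPK array and 1298 in the GFP array. MAP2K1, which encodes the ERK-activating kinase MEK1, was higher in the MAPK array (3393) than in the GFP array (1652). A probe set that lies outside a construct would not read it, so these values check no label. The median of the 17 pathway kinases was −0.21 in Akt, 0.14 in MAPK and 0.18 in PymT against GFP, within the range of random lists in each. PIK3R1, the regulatory subunit of phosphoinositide 3-kinase, was higher in PymT (2.06) and in MAPK (1.46), and the adaptor GAB1 was higher in MAPK (1.85), though other probe sets gave as little as 0.29 for PIK3R1 in PymT and 0.17 for GAB1. FYN, a Src family kinase, was 1.32 higher in MAPK, but −0.24 without probe sets marked as matching several transcripts.

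Genes induced by ERK signalling separated the arrays. Of 26 measured targets, 17 were at least 2-fold higher and none lower in the MAPK array than in GFP, with a median of 1.33, and 15 were higher and none lower in PymT, with a median of 1.11. In the Akt array 3 were higher and 4 lower, with a median of −0.37. EGR1, an immediate early transcription factor, read 13.8 in GFP, 204 in Akt, 3392 in MAPK and 426 in PymT, but its other probe sets gave −0.30 and 0.39 in Akt, 3.70 and 4.07 in MAPK and 0.83 and 2.32 in PymT. The ETS factor gene ETV4 was 4.57 higher in MAPK and 3.24 in PymT, and the ERK phosphatase gene DUSP5 was 3.52 and 3.23 higher. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, differed by −3.86 for Akt minus MAPK. The MAPK and PymT medians lay above all 10000 random lists and stayed apart under each of the 8 settings planned beforehand. With the second-brightest probe set of each gene, a setting chosen after seeing the data, they were 1.25 and 0.49 and still apart. The Akt value (percentile 0.11) lost its call there (−0.24) and without probe sets marked as matching several transcripts.

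**Figure D1:**
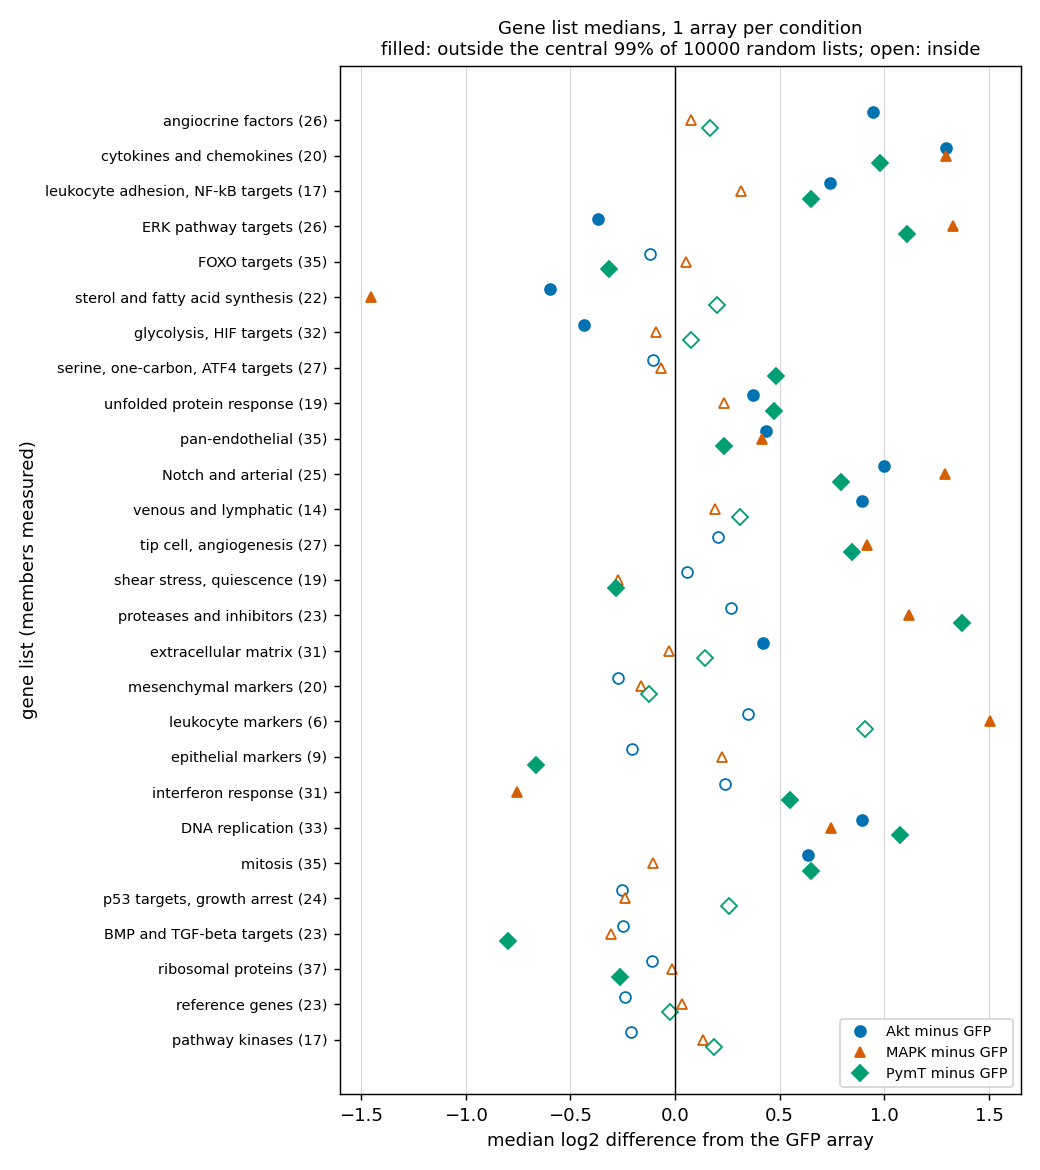
Median log2 difference from the GFP array (x axis) of the members of each gene list (y axis, with the number of members measured) for the Akt, MAPK and PymT arrays, 1 array each. Filled points lie outside the central range of 10000 expression-matched random lists, as the ERK target medians of 1.33 in MAPK and 1.11 in PymT do.

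The comparison of Akt with GFP asked which endothelial transcripts differ with Akt activation. The highest differences were those of AQP1, a water channel, at 5200.0 in Akt against 3.09 in GFP (8.36, and 4.802 in its other probe set), HEPH, a copper-dependent ferroxidase (7.41), and TIMP3, an inhibitor of matrix metalloproteinases (7.22). Of the 10 highest genes 9 read below the filter level of 50.3 in GFP, and of the 10 lowest 8 did so in Akt. Such readings are close to background, so the order and exact size of these differences are uncertain and depend on the offset. GJA4, the arterial gap junction protein connexin 37, read 12045 in Akt and 71.5 in GFP (7.16), and its second probe set gave 7.19. The Wnt modulator DKK2 (6.79), the leukocyte adhesion molecule VCAM1 (6.48), the selenium carrier SELENOP (6.14) and the zinc transporter SLC30A3 (5.99) were also higher, as were NAP1L3 (6.71) and TMTC1 (5.95). On the lower side stood the neuronal pentraxin NPTX1 (−7.34), osteopontin (SPP1, −5.82), CYTL1 (−5.73), the cadherin CDH6 (−5.51) and STK32B (−5.24). The hyaluronan receptor CD44 (−4.95), ANXA10 (−4.83), the retinaldehyde dehydrogenase ALDH1A3 (−4.65) and the synaptic vesicle protein SYT1 (−4.64) were lower too. Other probe sets gave −4.27 to −1.37 for CDH6 and −6.07 to −1.73 for CD44. Keratin 7 (KRT7) had the lowest value, −8.40, but its other probe set gave −0.08, so its difference rests on a single probe set. The same holds for HEPH, DKK2, NAP1L3, VCAM1, SELENOP, SLC30A3, NPTX1, SPP1, CYTL1, STK32B, ANXA10 and ALDH1A3, which had no other past the filter. In all, 1052 genes were at least 2-fold higher and 700 lower in Akt, and 135 and 54 at least 8-fold.

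Secreted factors that endothelial cells use to act on stem and progenitor cells, the angiocrine factors of the series title, had a median of 0.95 in Akt, above all random lists, with 11 of 26 measured members at least 2-fold higher and 4 lower. IGFBP2, a binding protein of insulin-like growth factors, read 9779.8 in Akt and 426 in GFP (4.48), RSPO3, which enhances Wnt signalling, 1209 and 116 (3.25), and fibroblast growth factor 2 (FGF2) 676 and 136 (2.21, and 1.61 in its other probe set). The Notch ligand JAG1 was 1.65 and ANGPT1, a ligand of the TIE2 receptor, 0.91 higher, whereas SPP1 gave −5.82, the greatest difference in the list, the placental growth factor PGF −2.64 (−0.24 in its other probe set), TGFB1 −1.70 (−0.92 in its other probe set), WNT5A −1.14 and stem cell factor (KITLG) −0.38. BMP4 differed by less than 2-fold, at 4241 in Akt and 4494 in GFP, and DHH, a hedgehog ligand, read 219 and 104. IGFBP2, RSPO3, SPP1, WNT5A, BMP4 and DHH had no other probe set past the filter. Members of this list may have been chosen by the study on these same arrays, so its count is not independent evidence. The median was −0.08 with a filter at the 75th percentile of expression, 0.41 without probe sets marked as matching several transcripts, and 0.42 with the second-brightest probe sets, in each case no longer apart from random lists.

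Endothelial identity lists were higher in Akt. Notch and arterial genes had a median of 0.996 (12 of 25 higher, 1 lower), with GJA4, DKK2, connexin 40 (GJA5, 5.82) and elastin (ELN, 2.95) at the top. Venous and lymphatic genes had a median of 0.89 (7 of 14 higher, 1 lower), led by the scavenger receptor STAB2 (4.27), the apelin receptor APLNR (3.70) and the lymphatic growth factor receptor FLT4 (3.25, and 0.86 in its other probe set). Pan-endothelial genes had a median of 0.44, with 11 of 35 higher and 2 lower, among them the diaphragm protein PLVAP (3.65), the adrenomedullin receptor subunits RAMP2 (3.43) and CALCRL (2.15), and CD34 (2.02). Tip cell and angiogenesis genes (0.20) and shear stress and quiescence genes (0.06) lay within the range of random lists, though the arginine synthesis enzyme ASS1 was 4.56 higher. With the mean over a gene's probe sets the tip cell median was 0.43 and apart from random lists.

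Among inflammatory genes, cytokines and chemokines had a median of 1.29 in Akt (11 of 20 higher, 3 lower), but −0.22 with the second-brightest probe sets. The alarmin IL33 read 5895 in Akt and 231 in GFP (4.60), the monocyte chemoattractant CCL2 was 3.24 higher, and TNFSF4 (OX40 ligand) gave −4.42. Leukocyte adhesion genes and NF-kB targets had a median of 0.74, with 7 of 17 higher and none lower, such as TNFAIP3, a brake on NF-kB signalling (2.21), and RELB (1.83). That call was lost with the second-brightest probe sets (0.69). Interferon response genes lay within range (0.24), although the antiviral protein BST2 was 3.20 higher. In the extracellular matrix list (median 0.42; 8 of 31 higher, 4 lower) the proteoglycan lumican (LUM) was 5.28 and periostin (POSTN) 3.32 higher. The proteases and their inhibitors lay just within range (0.27, percentile 99.4).

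Proliferation genes were higher and 2 metabolic lists lower in Akt. DNA replication genes had a median of 0.89 (16 of 33 higher, none lower), with E2F8 at 3.03 and the replication factor MCM10 at 2.67, and mitosis genes a median of 0.64 (11 of 35 higher, 1 lower), with the mitotic kinase CDK1 at 1.98. Sterol and fatty acid synthesis genes had a median of −0.59 (none of 22 higher, 4 lower), glycolysis and HIF targets −0.43 (3 of 32 higher, 4 lower, among them the phosphofructokinase PFKP at −1.68). The unfolded protein response list was 0.37 with no member 2-fold apart. FOXO targets (−0.12; 6 of 35 higher, 4 lower), serine, one-carbon and ATF4 targets (−0.11), p53 and growth arrest genes (−0.25), BMP and TGF-beta targets (−0.25), ribosomal proteins (−0.11) and reference genes (−0.24) lay within range. Of the FOXO targets, which Akt is known to repress through FOXO factors, the death ligand TNFSF10 was 2.97 and SESN3 2.47 higher. Of marker lists for other cells, the mesenchymal list had a median of −0.27 with members going both ways (7 of 20 higher, 5 lower): collagen genes COL3A1 (5.45) and COL1A2 (4.18) were higher and the fibroblast protease FAP (−2.88) lower. That median was 1.23, above all random lists, with the filter at the 75th percentile, and the BMP and TGF-beta median was −0.50 and apart without probe sets marked as matching several transcripts. Leukocyte (0.35) and epithelial (−0.21) markers lay within range, and the 3 measured erythroid markers, too few for a range, had a median of −0.27. The calls on cytokines, glycolysis and matrix genes were each lost under at least 1 alternative. With the second-brightest probe sets the calls on glycolysis and pan-endothelial genes were lost.

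**Figure D2:**
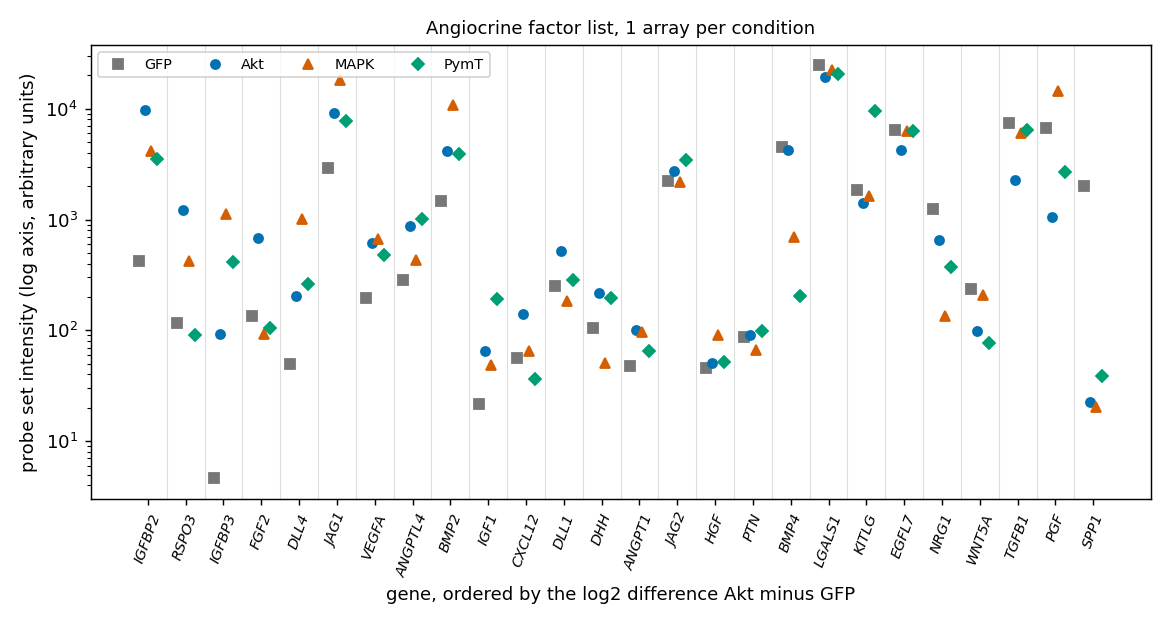
Probe set intensity (y axis, log scale, arbitrary units) of the 26 measured angiocrine list genes (x axis, ordered by the Akt minus GFP difference) in the GFP, Akt, MAPK and PymT arrays, 1 array each. IGFBP2 read 426 in GFP, 9779.8 in Akt, 4173 in MAPK and 3532 in PymT, while KITLG read 9524 in PymT against 1831 in GFP.

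The comparison of MAPK with GFP gave 1129 genes at least 2-fold higher and 874 lower (137 and 55 at least 8-fold). SELENOP read 10013 in MAPK and 28.1 in GFP (7.94), the desmosomal protein desmoplakin (DSP) was 7.42 higher, and EGR1 read 3392 against 13.8. The secreted glycoprotein stanniocalcin 1 (STC1) read 21774 against 184 (6.79), the stromelysin MMP10 28008 against 330 (6.35), and the D-type cyclin CCND2 5376 against 74.5 (5.95). HEPH (6.95), the surface glycoprotein CD24 (6.53), the insulin-like growth factor binding protein IGFBP3 (6.03) and NAP1L3 (5.77) were also among the 10 highest. Keratins 7 and 19 were lowest together with NPTX1: KRT7 at −7.57 (its other probe set at 0.39), NPTX1 at −7.03 and KRT19 at −6.10. The tetraspanin TSPAN8 (−6.03), SPP1 (−5.92), the forkhead factor FOXF1 (−4.46), ELAPOR1 (−4.82), C19orf33 (−4.60) and ADIRF (−4.44) were also lower. The other probe set of ELAPOR1 gave −1.75. SELENOP, DSP, MMP10, HEPH, IGFBP3, NAP1L3, NPTX1, KRT19, TSPAN8, SPP1, FOXF1, C19orf33 and ADIRF had no other probe set past the filter. Of the 10 highest genes 6 read below the filter level in GFP, and of the 10 lowest 4 did so in MAPK, so the order and exact size of those differences are uncertain.

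Sterol and fatty acid synthesis genes were lower in MAPK, with a median of −1.45 that lay below all random lists and stayed apart under each of the 8 settings planned beforehand and with the second-brightest probe sets (−1.13), and 13 of 22 members at least 2-fold lower against 1 higher. HMGCS1, an early enzyme of cholesterol synthesis, read 350.4 in MAPK and 3269 in GFP (−3.18), the fatty acid desaturase SCD 1086 and 8868 (−3.02), the sterol sensor INSIG1 857 and 6820.1 (−2.97), and the sterol oxidase MSMO1 differed by −2.36. Interferon response genes were lower as well (median −0.76; 14 of 31 lower, 3 higher), with the antiviral sensor OAS1 at −3.16, IFI44L at −2.80 and IFIT1 at −2.70, while CMPK2 was 2.03 higher. DNA replication genes were higher (0.75; 11 of 33 higher, none lower; CCNE2, a cyclin of S phase entry, at 2.71), whereas mitosis genes were not (−0.10), with securin (PTTG1) at −2.24 and the kinesin KIF20A at −1.89.

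Notch and arterial genes had a median of 1.29 in MAPK (14 of 25 higher, none lower), with GJA4 at 4.12, the Notch ligand DLL4 at 4.03 (1002 against 49.5) and the Notch target HEY1 at 3.05. Pan-endothelial genes had a median of 0.42 (9 of 35 higher, 3 lower), with PLVAP at 5.62 and the VEGF receptor FLT1 at 3.24 (−0.35 to 4.05 in its other probe sets). Tip cell and angiogenesis genes had a median of 0.92 (13 of 27 higher, 1 lower), with the TIE2 ligand ANGPT2 at 11816 against 308 (5.21), and proteases and inhibitors 1.12 (12 of 23 higher, 1 lower). Cytokines and chemokines had a median of 1.29 (13 of 20 higher, 3 lower), with TNFSF15 at 22674 against 661 (5.07) and interleukin 8 (CXCL8) at 3.81. The angiocrine list was within range (0.08; 8 of 26 higher, 3 lower), though IGFBP2 was 3.25 higher, and BMP4 read 695 in MAPK against 4494 in GFP.

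Other lists lay within range in MAPK: leukocyte adhesion and NF-kB targets (0.32), FOXO targets (0.05), glycolysis (−0.09), ATF4 targets (−0.07), unfolded protein response (0.23), venous and lymphatic genes (0.19), shear stress genes (−0.27), extracellular matrix (−0.03), p53 genes (−0.24), BMP and TGF-beta targets (−0.30), ribosomal proteins (−0.02) and reference genes (0.03). Leukocyte markers had a median of 1.503 (3 of 6 higher), with lysozyme (LYZ) at 773 against 3.85, and this call was lost with no filter and with a smaller offset. Mesenchymal (−0.16) and epithelial (0.22) markers were within range, and the erythroid median over 3 genes was 0.63. The tip cell call was lost without probe sets marked as matching several transcripts. Without them, FOXO targets (0.37) and BMP and TGF-beta targets (−0.67) lay apart from random lists. With the filter at the 75th percentile, BMP and TGF-beta targets lay apart on the other side (0.52), and shear stress genes at −0.46.

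In PymT, 1057 genes were at least 2-fold higher than in GFP and 669 lower (77 and 46 at least 8-fold). GNG2, a G protein gamma subunit, read 4296 against 10.6 (7.52, and 4.28 in its other probe set), the aggrecan-cleaving protease ADAMTS5 9028 against 41.8 (7.37), and STC1 16628 against 184 (6.40). The Src substrate CDCP1 (4.90), the protease ADAMTS1 (4.79), the fatty acid transport protein SLC27A3 (4.65), IGFBP3 (4.63), CCND2 (4.82), AQP1 (5.06, and 1.86 in its other probe set) and NAP1L3 (4.72) were also higher. Insulin receptor substrate 2 (IRS2, −5.04), the vasoconstrictor endothelin 1 (EDN1, 749.6 against 18306, −4.59), BMP4 (203 against 4494, −4.39) and the chemokine receptor CXCR4 (−4.10) were lower, as were AEBP1 (−4.83), CDH6 (−4.74), ZNF395 (−4.52), SPP1 (−5.28) and NPTX1 (−4.03). KRT7 was −6.16, with −0.15 in its other probe set. Other probe sets gave −4.99 and −1.56 for EDN1, −2.97 and −2.41 for CXCR4, −3.22 to −2.07 for CDH6 and −2.10 for ZNF395. SLC27A3, IGFBP3, NAP1L3, AEBP1, SPP1, NPTX1 and BMP4 had no other probe set past the filter. Of the 10 highest genes 5 read below the filter level in GFP, and of the 10 lowest 5 did so in PymT, with the same uncertainty of order and size. In this array the dap and thr labelling controls had 3'/5' ratios of 28.1 and 40.1, against 5.11 and 19.2 in GFP. Whether these control probe sets read above background was not checked.

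Proteases and their inhibitors had a median of 1.37 in PymT (13 of 23 higher, 1 lower), with ADAMTS9 at 3.56 (0.86 and 2.03 in its other probe sets) and MMP10 at 3.19 beside ADAMTS5 and ADAMTS1. Tip cell and angiogenesis genes had a median of 0.85 (11 of 27 higher, 4 lower), and BMP and TGF-beta targets −0.80 (none of 23 higher, 11 lower), with TGFBI at −3.88, follistatin (FST) at −3.02, the matricellular CCN2 at −2.65 and BMP6 at −2.23. FOXO targets were lower (−0.32; 3 of 35 higher, 8 lower; IRS2, CXCR4 and CITED2 at −1.73). ATF4 and serine synthesis genes were higher (0.48; 6 of 27 higher, 3 lower), with asparagine synthetase (ASNS) at 3.11 and the pseudokinase TRIB3 at 2.50. The unfolded protein response list was 0.47 (2 of 19 higher, SDF2L1 at 1.80 and MANF at 1.02). DNA replication genes had a median of 1.07 (19 of 33 higher, none lower; CDC6 at 2.97) and mitosis genes 0.65 (5 of 35 higher, 2 lower). Sterol and fatty acid synthesis genes lay within range (0.20), and glycolysis genes too (0.08).

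Interferon response genes were higher in PymT (0.55; 9 of 31 higher, none lower; ISG20 at 2.68, OAS2 at 2.25, with 0.12 and 1.77 in its other probe sets), and so were leukocyte adhesion and NF-kB targets (0.65; 8 of 17 higher, 1 lower; BCL2A1 at 3.19, E-selectin, SELE, at 2.44). Cytokines had a median of 0.98 (10 of 20 higher, 1 lower; IL32 at 3.57), with −0.04 for the second-brightest probe sets. The Notch and arterial median was 0.79 (10 of 25 higher, 3 lower), and pan-endothelial genes gave 0.24 (8 of 35 higher, 2 lower). The angiocrine median was 0.17 (9 of 26 higher, 5 lower), with KITLG at 2.37 (0.97 in its other probe set), but it was 0.61 and apart from random lists with the filter at the 75th percentile and without probe sets marked as matching several transcripts. Shear stress genes were −0.28, epithelial markers −0.66 and ribosomal proteins −0.26, and each of these calls was lost under at least 2 alternatives. The calls on cytokines, ATF4 targets, NF-kB targets, tip cell and pan-endothelial genes were lost under at least 1. Venous and lymphatic (0.31), extracellular matrix (0.14), mesenchymal (−0.12), leukocyte (0.91), p53 (0.26) and reference (−0.02) lists were within range, and the erythroid median was 0.58. The extracellular matrix median lay apart under 3 of the 8 planned settings, at 0.33 under quantile normalization. With the second-brightest probe sets the angiocrine median also lay apart, at 0.67. With the second-brightest probe sets, calls were lost on BMP and TGF-beta targets (−0.25), interferon genes (0.18), mitosis genes (0.42), the unfolded protein response (0.26), ATF4 targets (0.30), tip cell (0.40), pan-endothelial (0.12) and shear stress genes (−0.53) and ribosomal proteins (−0.28).

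**Figure D3:**
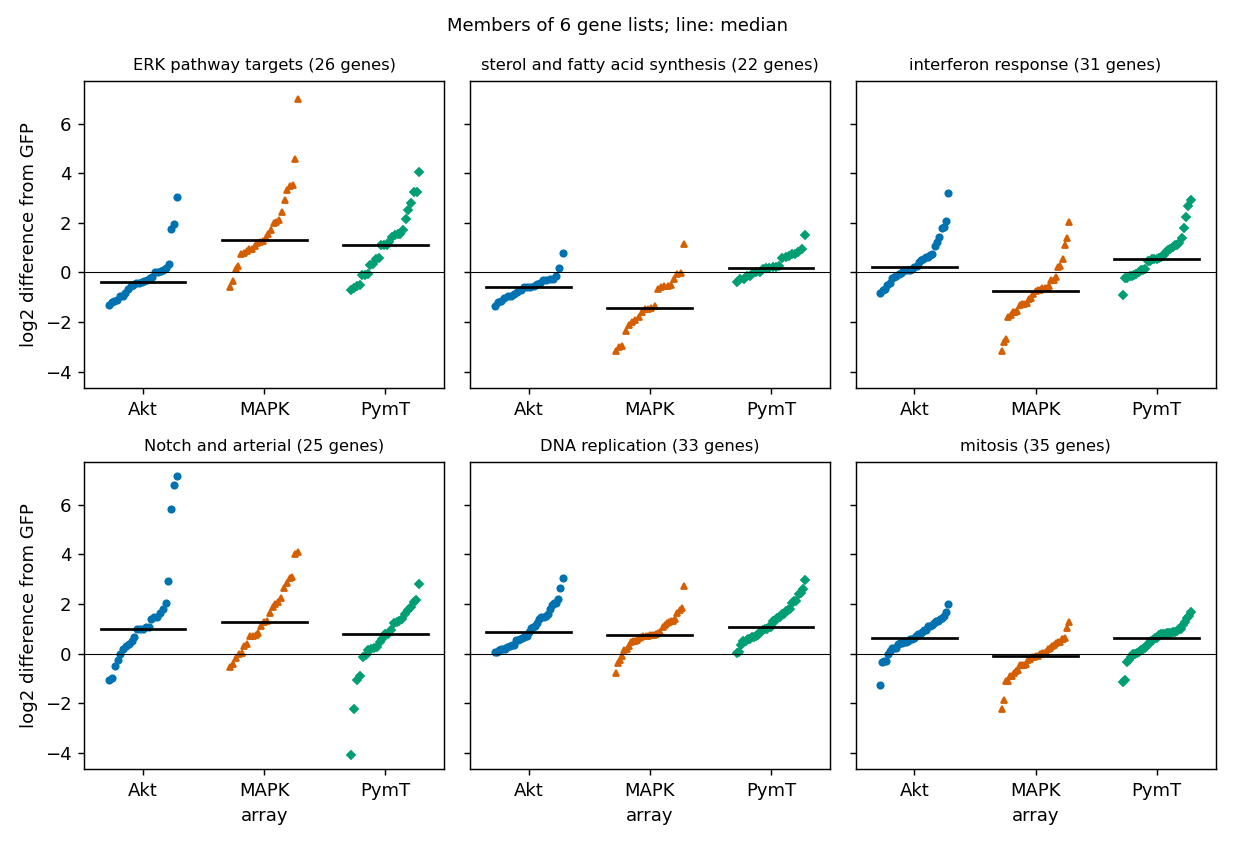
Log2 difference from GFP (y axis) of every measured member of 6 gene lists in the Akt, MAPK and PymT arrays (x axis), 1 array each, with a line at the list median. Of 22 sterol and fatty acid synthesis genes, 13 lie at least 2-fold below GFP and 1 above it in MAPK (median −1.45), and the median in PymT is 0.20.

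Set directly against each other, the Akt and MAPK arrays had 950 genes at least 2-fold higher in Akt and 941 lower. APLNR (6.51), the collagen COL14A1 (6.06), PLAC9 (6.06), TMEM100 (5.29) and POSTN (5.06) were higher in Akt, and STC1 (−6.93), MMP10 (−6.56), PLEK2 (−5.95), ANGPT2 (−5.81) and TNFSF15 (−5.37) were lower. Of the 5 highest, 4 read below the filter level in MAPK, and of the 5 lowest 1 did so in Akt, so the exact sizes are uncertain. ERK targets had a median of −1.84 with 20 of 26 lower in Akt, while interferon genes (1.38; 16 of 31 higher, 1 lower) and mitosis genes (0.91; 13 of 35 higher) were higher in Akt. Sterol synthesis genes had a median of 0.69, with SCD at 2.76. Venous and lymphatic genes gave 0.90, a call lost with the second-brightest probe sets (0.62). DNA replication genes lay within range (0.21). FGF2 was 2.70 and BMP4 2.59 higher in Akt than in MAPK, whereas the angiocrine list as a whole gave 0.08. Notch and arterial genes lay within range (0.20; 4 of 25 higher, 6 lower). Extracellular matrix genes (0.39) were called higher in Akt, and glycolysis genes (−0.35), proteases and inhibitors (−0.40), leukocyte markers (−1.30), the pathway kinases (−0.47) and reference genes (−0.29) lower. Each of these calls was lost under at least 1 planned setting, that on reference genes under 5 of 8.

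PymT against Akt gave 903 genes at least 2-fold higher and 879 lower, and PymT against MAPK 899 and 829. Against Akt, STC1 (6.54), GNG2 (6.48), CDCP1 (5.81), ADAMTS5 (5.80) and the thrombin inhibitor SERPIND1 (5.19) were higher. Other probe sets gave 3.01 for GNG2, and 3.73 and 4.15 for CDCP1. COL3A1 (−9.07), the guanylate cyclase subunit GUCY1A1 (−7.51), POSTN (−7.34), SELENOP (−7.18) and FBLN2 (−6.02) were lower. Against MAPK, APLNR (7.35), PMCH (5.81), ADIRF (4.92) and BEX5 (4.70) were higher, and SELENOP (−8.99), COL3A1 (−7.75), DSP (−7.22), CXCR4 (−7.19) and CD24 (−6.43) lower. Against Akt, 1 of the 5 highest read below the filter level in Akt and 5 of the 5 lowest in PymT, and against MAPK 2 of the 5 highest did so in MAPK and 3 of the 5 lowest in PymT, so these sizes and orders are uncertain. ERK targets were higher in PymT than in Akt (1.30; 18 of 26) and lower than in MAPK (−0.74; 7 of 26). Notch and arterial genes were lower in PymT than in Akt (−0.61; 9 of 25 lower, 3 higher) and than in MAPK (−0.51; 11 lower, 2 higher). BMP and TGF-beta targets were lower in PymT than in Akt (−0.85) and than in MAPK (−0.76), and FOXO targets likewise (−0.52 and −0.47). Growth arrest and p53 target genes were higher (0.59 and 0.44, the latter call lost without probe sets marked as matching several transcripts), and sterol synthesis genes were 0.85 and 1.59. With the second-brightest probe sets the calls on ERK targets against MAPK (−0.57), Notch genes against Akt (−0.25), BMP and TGF-beta targets against Akt (−0.0014) and growth arrest and p53 genes against both (0.27 and 0.28) were lost. KITLG was 2.75 higher than in Akt and 2.54 higher than in MAPK, with 1.54 and 0.95 in its other probe set.

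Other lists called apart in these pairs were ATF4 targets (0.65 against Akt, 0.42 against MAPK), shear stress genes (−0.47 and −0.34), mitosis genes (−0.23 and 0.76) and ribosomal proteins (−0.16 and −0.23). Against Akt alone, glycolysis genes (0.33), proteases and inhibitors (0.65) and the pathway kinases (0.53) were called higher, and venous and lymphatic genes (−0.81) and extracellular matrix genes (−0.23) lower. Against MAPK alone, interferon genes (1.28; 20 of 31 higher, none lower) and DNA replication genes (0.43) were called higher. Of these calls, those on ATF4 targets against Akt and on mitosis, interferon and DNA replication genes against MAPK held under all 8 planned settings, and the others were lost under at least 1. With the second-brightest probe sets the mitosis call against MAPK was also lost (0.37). DNA replication genes lay within range against Akt (0.34), but apart under 1 planned setting.

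The 3 differences from GFP were compared across genes, which are not independent replicates. Their correlations were 0.55 for Akt with MAPK, 0.47 for Akt with PymT and 0.54 for MAPK with PymT. A simulation of unchanged arrays against the same GFP array gave 0.50 for each, which follows from giving all arrays equal noise. The covariances were 0.43, 0.33 and 0.39, against a simulated 0.36. The simulation takes all of the difference between the Akt and MAPK arrays as noise and gives the GFP array the same noise. It is an upper bound only if the GFP array is no noisier than the Akt and MAPK arrays, which was not tested. Genes at least 2-fold higher in both numbered 518, 482 and 543, where independent lists would share 95.5, 89.4 and 96.0 and the simulation about 420. Genes lower in both numbered 294, 224 and 269, against 49.2, 37.7 and 47.0 for independent lists and about 418 in the simulation. The lower counts thus lie below what the shared GFP array gives in that simulation. Part of the excess of the higher counts over independent lists may come from the shared GFP array. Between differences that share no array, the correlations were −0.15 for Akt minus GFP with PymT minus MAPK, −0.06 for MAPK minus GFP with PymT minus Akt, and 0.09 for PymT minus GFP with MAPK minus Akt, with simulated values near 0.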

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

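The gene comparisons of the report do not use the measurements in this part, which were looked at after the main results were seen. The control ratios are also given with the PymT results and in the paragraph on sterol genes below. Among 3940 probe sets past the expression filter without a single gene name, 246 were at least 2-fold higher in Akt than in GFP, 260 in MAPK and 209 in PymT, and 239, 320 and 322 lower in the same order. Of the 12434 named genes, 14.1%, 16.1% and 13.9% were at least 2-fold apart in that order, a higher share each time. The 3'/5' ratio of the dap labelling control was 28.11 in the PymT array, against 5.11 in GFP, 2.10 in Akt and 3.66 in MAPK. For the thr control it was 40.14 in PymT, against 19.2, 4.50 and 5.14 in the same order. These ratios may rest on dim readings, since the control intensities were not compared with background.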

How the results depend on the processing

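The second-brightest probe set and the comparisons it enters were chosen only after the data were seen, and the other alternatives were planned. The count of genes at least 2-fold apart depended on the filter and threshold. For Akt against GFP, MAPK against GFP, PymT against GFP, Akt against MAPK, PymT against Akt and PymT against MAPK, in that order, it was 3289, 3615, 3154, 3386, 3216 and 3230 with no filter, where more and dimmer genes enter. With a filter at the 75th percentile it was 765, 952, 819, 990, 846 and 805, and at least 3-fold apart were 780, 850, 680, 766, 751 and 716. Of 78 list medians called apart, 45 kept their call under all 8 settings planned for them, 33 lost it under at least 1, and 2 changed sign. Of 84 medians within range, 15 came to lie apart under at least 1 setting and 38 changed sign. Of 680 differences of genes eligible to be named, 136 moved by over 1.5-fold with the offset at the pooled median and 146 with the mean over a gene's probe sets. The sign changes of called medians were those of ribosomal proteins in PymT against MAPK (0.0135 under quantile normalization) and of the angiocrine list in Akt against GFP (−0.0831 with the filter at the 75th percentile); the cause was not tested. Under that filter the correlation of MAPK minus GFP with PymT minus Akt was 0.0726. Without probe sets marked as matching several transcripts, FYN in MAPK against GFP became −0.238 and KRT7 0.392, while KRT7 was −0.0699 for PymT against Akt and −0.546 for PymT against MAPK, because another probe set then stands for the gene. With the second-brightest probe set, 38 of 75 called medians kept their call, 35 lost it and 2 changed sign, and 6 within range came to lie apart. The 2 were cytokine medians of −0.219 in Akt and −0.0438 in PymT against GFP. No paired analysis was possible because each condition had 1 array. Leaving out a replicate was not possible for the same reason. Dim genes are limited by signal over background, since no detection calls were used and intensities near the filter (about 50.3) are close to background.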

Other observations

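The tests in this part were chosen after the results were seen, except that on other probe sets of the collagen genes, whose bound was written before its result. The second-brightest probe set was chosen after the data were seen, though its bound was written before its result. The bounds for the mesenchymal marker median, for the correlation between PymT and MAPK and for RNA quality were made stricter after their values were seen.

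Some genes differed from GFP in the same direction in all 3 other arrays, and those named here were chosen after their values were seen. CCND2, the D-type cyclin, read 74.5 in GFP, 2450.2 in Akt, 5376 in MAPK and 2449 in PymT, and PLVAP, a protein of endothelial diaphragms, 129.5, 1771, 7006 and 2246. LITAF, which takes part in lysosomal sorting, read 51.6 in GFP and 2937, 1163 and 670.2 in the others. The matrix protein TGFBI was lower in each, at 3438 in GFP against 186, 155 and 221, as was the metallothionein MT1E, at 4969 against 739, 610.0 and 485.

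Of 3 further genes, also chosen after their values were seen, CDKN2A, the locus of p16, read 1605 in GFP and 1451 in PymT but 179 in Akt and 398 in MAPK. CDKN2B, which encodes p15, read 515 in GFP, 108 in Akt, 4297 in MAPK and 288 in PymT. DDIT4, an inhibitor of mTOR signalling, read 6479 in GFP, 12070 in Akt, 883 in MAPK and 9057 in PymT.

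The genes at least 2-fold higher in all 3 other arrays than in GFP numbered 319, against 191 to 229 when another array is set as the odd array out. This exceeds the others by less than the bound of 1.5 times set for it. An odd GFP array would raise this count as a shared response would. The count therefore cannot tell them apart at any size, and no conclusion is drawn from the bound. For genes at least 2-fold lower in all 3, the count of 139 is below the 148 to 239 of the other arrays, so nothing sets GFP apart there. Over both directions the counts were 458 with GFP as the odd array, 435 with Akt, 454 with MAPK and 339 with PymT. Different donors may add to these counts: the Akt and MAPK arrays had 1891 genes at least 2-fold apart, within the 1726 to 2003 of the other pairs, which leaves donor open because treatment could part them too. A shared response to activation stays among the open explanations, as untested.

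Some collagen and proteoglycan genes, picked after their values were seen, were higher in the Akt array, with COL3A1 at 10784 against 234 in GFP, LUM at 3014 against 64.9 and COL1A2 at 1914 against 93.3, while of the whole extracellular matrix list 8 of 31 were higher and 4 lower. A single odd probe set per gene is argued against, because 6 of 6 other probe sets of COL3A1, LUM, DCN and COL1A2 were also at least 2-fold higher. Fibroblasts or smooth muscle cells in the culture could bring such transcripts, but the mesenchymal list had a median of −0.27, with 7 of 20 members higher and 5 lower. ACTA2 read 610 against 773 and TAGLN 216 against 492, but these are members picked from that list, which also holds COL3A1, LUM and COL1A2. The list median reached 1.23 with the filter at the 75th percentile, so contaminating cells stay open. Akt activation and donor are open too, as untested.

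Sterol and fatty acid synthesis genes were lower in the MAPK array, with a median of −1.45. RNA or labelling quality stays open. The 3'/5' ratio of beta-actin was highest in PymT (1.61, against 1.57 in MAPK), where the median was 0.20, but that of GAPDH was highest in MAPK (1.22). In Akt the median was −0.59, and the ratios were lower than in GFP (beta-actin 1.30 against 1.49, GAPDH 0.92 against 1.05). The list median thus followed neither ratio over the 4 arrays, but 1 array per condition does not settle the question. The labelling controls cannot settle it, because whether their probe sets read above background was not checked. The dap, lys, phe and thr ratios were higher in PymT (28.1, 2.55, 2.997 and 40.1) than in MAPK (3.66, 2.03, 1.68 and 5.14). In GFP, lys and phe were lower (1.52 and 1.20) and dap and thr higher (5.11 and 19.2) than in MAPK. Choice of probe set is argued against by a median of −1.13 over 15 genes with a second-brightest probe set. Under quantile normalization the median was −1.47. The arrays already shared a trimmed mean, so that step could move the median little, and no conclusion on array scaling is drawn from it. MAPK activation and a donor difference may each account for the pattern, and 1 array per condition leaves both open and untested.

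A common downstream response of PymT and MAPK was a hypothesis tested by the correlation of PymT minus GFP with MAPK minus Akt, which share no array. It was 0.088, with 0.054 to 0.143 under the alternatives, which neither excludes nor shows such a response across all genes. ERK targets, set beside it after their values were seen, were higher in PymT than in GFP (median 1.11) and lower in Akt than in MAPK (−1.84). Among all genes, the strongest correlation of differences that share no array was −0.15, for Akt minus GFP with PymT minus MAPK. That value pairs Akt with MAPK and GFP with PymT instead, so the question stays open.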
